A study of Rattus norvegicus with 9 samples.

How the data were processed

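Stranded mRNA libraries were made from primary neonatal rat ventricular myocytes infected with an adenovirus for GFP, Nfya or Nfe2l1, with 3 libraries per virus and 9 in all. Per the labels, the cells were kept in medium with 3% fetal bovine serum for 48 h before infection and collected after a further 48 h in serum-free medium. The labels number the libraries 1 to 3 within each virus and do not say whether a number joins libraries of different viruses or whether replicates came from separate cultures.

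The authors deposited a table of whole-number counts for 28935 gene symbols, of which 6798 had no count in any library. The authors also deposited RPKM values for 14986 genes (reads scaled by gene length and library size). The column Length of that table is, per the file headers, the gene length in bases. For each virus against GFP the authors deposited an edgeR table whose logFC and logCPM columns are log2 values. Its LR column holds, per the file headers, the score of a likelihood ratio test, and its PValue and FDR columns hold the p-value and adjusted p-value deposited by the authors. The processing notes name FastQC 0.11.4, featureCounts 1.6.0 and edgeR 3.20.5 and the builds rn6, mm10 and GRCm38. The aligner, trimming, handling of duplicate reads, strand setting and annotation are not given in the sources used here. No coordinates are therefore given for any gene, and a newer rat gene table served only to match gene names. The genes in the deposited edgeR tables (14438 for Nfya and 14516 for Nfe2l1) are those with CPM above 1 in at least 3 of the 6 libraries compared, as tested on the count table. At an FDR below 0.05 these tables hold 3913 higher and 3368 lower genes for Nfya and 4072 higher and 4161 lower genes for Nfe2l1. Of the genes called both there and here, 6686 for Nfya and 8017 for Nfe2l1, 6686 and 8017 have the same direction.

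Raw counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with the groups as given (14151 genes), scaled by TMM and tested with the quasi-likelihood F test in a single fit of all 9 libraries, with group as the only term. Each virus was compared with GFP, and the Nfya-labelled with the Nfe2l1-labelled libraries. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over the genes tested. Standard errors of log2 fold changes were computed as the absolute log2 fold change over the square root of F. For large changes from few counts this value falls below the counting error, as for Tubb4a in Nfe2l1 against GFP (24 counts in GFP, ± 0.14). Library totals ranged from 5712123 to 7310774 counts, which limits precision for genes with few counts. A gene with 0 counts in a group is given as at least N-fold against a floor of 3 counts over the group, and a gene with 1 to 3 counts as a count ratio scaled by library size, with its 95% exact (Clopper-Pearson) interval.

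The choices of test, lists, named genes and alternatives were made before the data were examined, except where stated. The named genes were Nfya and Nfe2l1, and, for each virus against GFP, the 10 called genes with the largest rise and the 10 with the largest fall among those with a mean of at least 5 CPM in the higher group, no overlap between the libraries of the groups compared and a standard gene symbol. For Nfya against Nfe2l1 the 5 largest in each direction were taken. Up to 4 members with the smallest p were taken from each called list and up to 2 from each other list, and examples in the text come from these. The overlap paragraph names Lexm and Gpx2 from genes already named by this rule.

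The lists comprised 26 functional and 7 cell type lists with 867 different genes, of which 838 were found in the count table, 16 of them through the gene name table. The functional lists were NF-Y subunits, CNC factors and small Maf, G1/S and DNA replication, G2/M and mitosis, proteasome subunits, ubiquitin and ER-associated degradation, antioxidant and glutathione, iron handling, ER chaperones and unfolded protein response, ATF4 and amino acid response, cytosolic heat shock, cholesterol synthesis, fatty acid and lipid synthesis, sarcomere, fetal and stress cardiac genes, calcium handling and excitation, fatty acid oxidation, oxidative phosphorylation, glycolysis, p53 targets, apoptosis regulators, interferon response, NF-kB and inflammatory mediators, cytosolic ribosomal proteins, autophagy and lysosome, and collagens and extracellular matrix. The cell type lists held fibroblast, endothelial, smooth muscle and pericyte, macrophage and leukocyte, epicardial and mesothelial, Schwann and neural, and erythroid markers. They were tested with camera at a preset correlation of 0.01, which compares a list with all other genes, and adjusted over the 33 lists of a comparison. Camera with an estimated correlation and fry were alternatives; fry asks whether the genes of a list move, on balance, in 1 direction and makes no comparison with other genes. Not every list member chosen by the naming rule is named in the text, and 1 of them is not reported here.

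The pipeline was tested on simulated data of the same design. Of 50 genes changed 1.25-fold, 1.5-fold, 2-fold or 4-fold, it recovered 33, 44, 47 and 48 in the right direction for Nfya against GFP, 35, 43, 44 and 48 for Nfe2l1 against GFP and 31, 47, 45 and 50 for Nfya against Nfe2l1. It called 9 of 13760, 7 of 13751 and 6 of 13741 unchanged genes. The simulated counts were independent, with their spread taken from these data, only 200 genes changed and no count ceiling. These rates therefore show that the pipeline works on such data and do not measure its errors on the real libraries.

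The alternatives were RLE size factors, library size only, a weaker and a stricter filter on low counts, a DESeq2 1.42.0 Wald test, limma-voom, a fit of only the 6 libraries compared, a replicate block, an adjusted p of 0.01, an added minimum of 1 for the absolute log2 fold change, limma-trend on the deposited RPKM values with pseudocounts of 1 and 0.1 and with or without a minimum mean RPKM of 1, the targeted genes left out, and each library left out in turn. An inversion of the count ceiling (1.6 counts per base) was chosen after the data were seen. RPKM values entered only these alternatives, since counts allow a count model, and lengths served to express counts per base. Simulations of shared controls were run 20 times. Permutation tests used 100000 permutations. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.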

Results

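Messenger RNA was sequenced from 9 libraries of neonatal rat ventricular myocytes, primary heart muscle cells taken from Sprague-Dawley rats in the days after birth. The cultured cells carried an adenovirus for GFP (the negative control), Nfya or Nfe2l1, with 3 libraries per virus. NFYA is the DNA-binding regulatory subunit of NF-Y, a factor that binds CCAAT boxes and is known for its role at cell cycle promoters. NFE2L1 is a transcription factor of the cap'n'collar family, known for inducing proteasome genes. The series asks how the transcriptome of these myocytes changes when either factor is overexpressed. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values below measure only the spread between these libraries, which may be technical. The GFP libraries held 6543084, 6782414 and 5712123 counts in replicates 1, 2 and 3. The Nfya-labelled libraries held 6482108, 6541937 and 6660358 counts, and the Nfe2l1-labelled libraries 6492769, 6479766 and 7310774. Of 28935 genes in the count table, 14151 had enough counts to be tested, and these carried 99.8% of all counts. Levels are given as counts scaled to library size (CPM), as mean ± SD over the 3 libraries of a group, and changes as log2 fold change ± SE. This SE is derived from the test score and understates the error of large changes from few counts. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules.

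Coverage was dense in a part of the genes. Mean counts per base of gene length reached 1.45 at most, only 14 genes exceeded 1, and 708 genes with 13.4% of the counts exceeded 0.5. Within the GFP group, the shallowest library (replicate 3) held a larger share of its counts in these 708 genes than the deepest (replicate 2), by 0.24 on the log2 scale relative to 3867 sparsely covered genes. The same difference was 0.22 between replicates 2 and 3 of the Nfe2l1-labelled group. It was -9.04e-04 between replicates 1 and 3 of the Nfya-labelled group, whose depths differed by a factor of only 1.03. With an assumed ceiling of 1.6 counts per base inverted, an alternative chosen after the data were seen, the log2 fold changes of called genes above 0.5 counts per base had slopes of 1.25, 1.26 and 1.27 against the values from the counts as deposited, for Nfya against GFP, Nfe2l1 against GFP and Nfya against Nfe2l1. The differences of 0.24 and 0.22 were near or above the log2 ratios of library totals, 0.248 (GFP) and 0.174 (Nfe2l1). The inversion may therefore correct too little, and whether it removes these differences was not tested. Among the genes named below, Nfe2l1, Hmox1, Bag3, Psmb3, Psmc5, Psmd3, Psme4, Xirp1, Acadvl, Col1a1, Tubb5, Tubb6, Tuba4a and Kif5b lay above 0.5 counts per base.

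**Figure D1:**
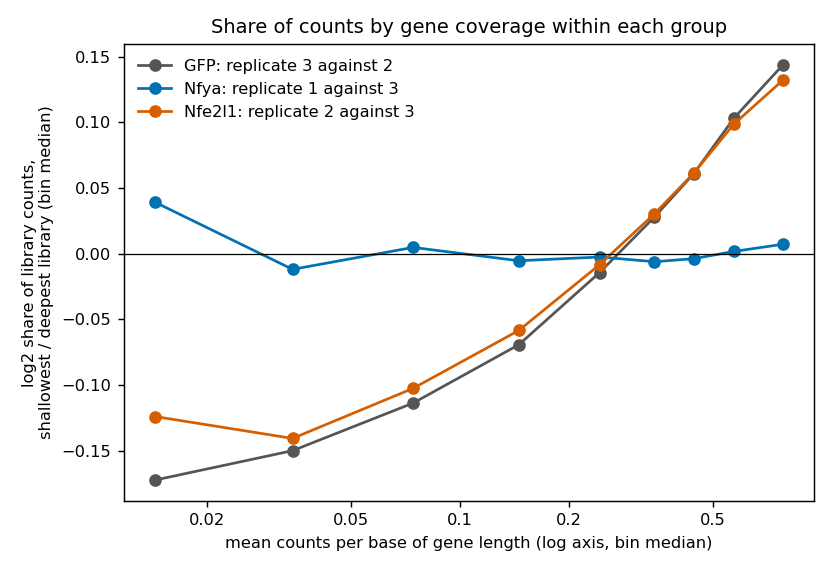
The x axis gives mean counts per base of gene length (log axis, median of each bin of genes) and the y axis the median log2 ratio of a gene's share of the library's counts, shallowest over deepest library of a group. Each line is 1 group; GFP and Nfe2l1 rise with coverage, with dense minus sparse differences of 0.24 and 0.22, and Nfya stays near 0.

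The targeted transcripts were examined in every library. Nfya stood at 80.4 ± 2.19 CPM in GFP, 89.0 ± 0.683 CPM in the Nfya-labelled libraries and 92.3 ± 2.20 CPM in the Nfe2l1-labelled libraries (SD, n = 3 each). It was 1.11-fold higher in the Nfya-labelled libraries than in GFP (log2 fold change 0.15 ± 0.04, adjusted p = 0.00926) and 1.15-fold higher in the Nfe2l1-labelled ones (0.20 ± 0.04, adjusted p = 2.06e-04). Between the Nfya- and Nfe2l1-labelled libraries the Nfya transcript differed by -0.05 ± 0.04, which did not pass the test (adjusted p = 0.361). Nfe2l1 stood at 240.7 ± 6.09 CPM in GFP, 222.7 ± 4.79 CPM in the Nfya-labelled libraries and 239.4 ± 6.14 CPM in the Nfe2l1-labelled libraries. Its change in the Nfe2l1-labelled libraries was -0.01 ± 0.03 (adjusted p = 0.856), and in the Nfya-labelled libraries it fell by 0.11 ± 0.03 against GFP (adjusted p = 0.00784) and by 0.10 ± 0.03 against the Nfe2l1-labelled ones (adjusted p = 0.0120). With DESeq2 these calls were lost, at adjusted p = 0.0843 for Nfya in the Nfya-labelled libraries and 0.102 and 0.115 for the falls of Nfe2l1. The fall of Nfe2l1 against GFP was also lost without GFP replicate 1 (adjusted p = 0.137), Nfe2l1 replicate 1 (0.0892) or Nfe2l1 replicate 3 (0.0671), with genes of at least 5 mean CPM (0.0797) and with only the 6 libraries compared (0.0798). Its fall against the Nfe2l1-labelled libraries was lost without GFP replicate 1 (0.0611), Nfe2l1 replicate 1 (0.107) or Nfya replicate 1 (0.0622), and at a threshold of 0.01. Over the 23 alternatives the adjusted p ran from 7.34e-04 to 0.0843 for Nfya in the Nfya-labelled libraries against GFP, and from 0.00276 to 0.137 and 0.00206 to 0.115 for these falls of Nfe2l1. The authors' deposited tables give 0.18 for Nfya in the Nfya comparison and -0.01 for Nfe2l1 in the Nfe2l1 comparison. Since Nfya was not called above its level in the other virus group, nor Nfe2l1 above its level in GFP, the groups are named by their labels, and every direction below rests on those labels.

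**Figure D2:**
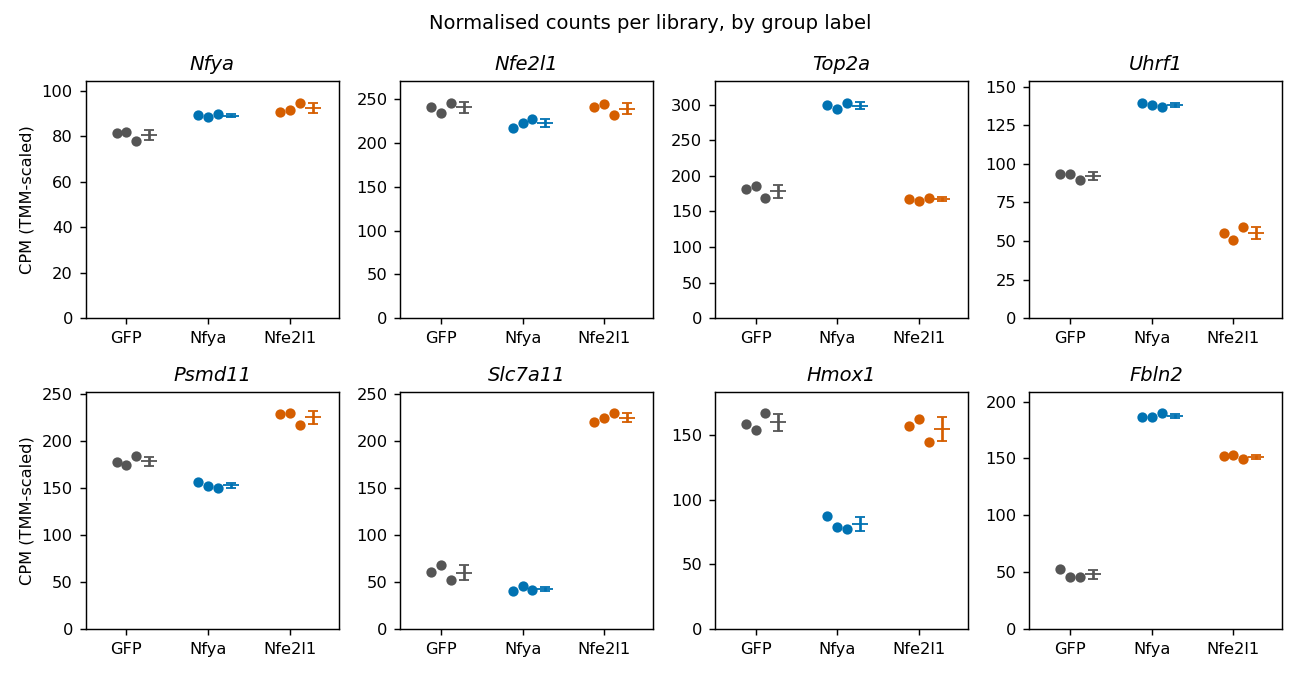
Each panel plots 1 gene, with TMM-scaled CPM on a y axis from 0 and the 3 group labels on the x axis. Points are single libraries and bars the mean ± SD (n = 3); Nfya spans 77.8 to 94.8 CPM over all 9 libraries, while Slc7a11 has means of 42.5, 60.0 and 224.9 CPM in the Nfya, GFP and Nfe2l1 groups.

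In Nfya-labelled libraries against GFP, which asks what NFYA overexpression changes, genes of mitosis and of the extracellular matrix were higher. Of 34 antioxidant genes 22 were lower, though the call of their list was lost with an estimated correlation (adjusted p = 0.764). Top2a, the DNA topoisomerase of dividing cells, rose from 178.3 ± 8.84 to 298.9 ± 4.62 CPM (SD, n = 3 each). The matrix glycoprotein gene Tnc rose from 149.6 ± 8.23 to 464.9 ± 1.83 CPM, and Fbln2, which codes for a fibulin of elastic fibres, from 48.0 ± 3.93 to 187.5 ± 1.94 CPM. Hmox1, the heme-degrading enzyme and a classical oxidative stress gene, fell from 160.2 ± 6.54 to 81.3 ± 5.23 CPM. Over all genes, edgeR called 3433 higher and 3953 lower at adjusted p below 0.05, of which 916 and 481 changed at least 2-fold; the median absolute log2 fold change of called genes was 0.37. More genes were higher than lower in 9 of 24 alternatives (3823 and 3329 with only the 6 libraries compared), so the balance of directions is not settled. The libraries of the 2 groups did not overlap in 8719 genes (61.6%), where chance gives 10%.

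Among the 10 largest rises in the Nfya-labelled libraries, Hgf, the hepatocyte growth factor gene, rose 13.9-fold from 2.36 ± 0.711 to 33.3 ± 3.31 CPM (log2 fold change 3.80 ± 0.16, adjusted p = 2.10e-11). The collagen gene Col6a6 rose 12.2-fold (3.61 ± 0.21), the matrix-associated gene Fndc1 9.73-fold (3.28 ± 0.11), the sodium channel gene Scn7a 9.71-fold (3.28 ± 0.28) and Islr 9.51-fold (3.25 ± 0.17). The mesothelin gene Msln rose 9.22-fold. Ces2g (14.9-fold), Cntn6 (10.4-fold), Lhfpl1 (10.1-fold) and Cpz (log2 fold change 3.17 ± 0.18) complete the 10 largest rises, and Ces2g has close paralogs, so its count is uncertain. Among the largest falls, the serotonin receptor subunit gene Htr3a fell from 73.8 ± 1.85 to 4.39 ± 0.406 CPM (log2 fold change -4.07 ± 0.09, adjusted p = 2.67e-14), and Tmem200c fell from 43.7 ± 4.23 to 1.32 ± 0.852 CPM (-5.04 ± 0.19). Apoa2, an apolipoprotein gene, had 112 counts in GFP and 0 in the Nfya-labelled group, which makes it at least 39.0-fold lower against a floor of 3 counts over the group. Clec18a had 110 counts in GFP and 2 in the Nfya-labelled group, a ratio of 57.5 with a 95% exact counting interval of 15.5 to 480.8. The lymphocyte adhesion gene Cd2 (-3.86 ± 0.32), Cpne6 (-3.82 ± 0.34), Lexm (-3.71 ± 0.24), Zfp804a (-3.59 ± 0.48) and Vwa2 (-3.39 ± 0.24) also fell. Hspa1b, an inducible HSP70 gene, fell by 3.38 ± 0.60, but its GFP libraries spread from 50.4 to 248.8 CPM and it has a near-identical paralog, so the size of this fall is uncertain.

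Among the 33 lists fixed before the data were examined, 9 were called by camera in this comparison, 7 higher and 2 lower. Collagens and extracellular matrix genes led: 29 of 34 tested members rose and 1 fell (30 and 1 adjusted over the list alone), with a median log2 fold change of 0.65 (adjusted p = 3.40e-65). Fbn1, the fibrillin gene, rose by 1.18 ± 0.03 and Postn, the periostin gene, by 1.29 ± 0.03. Of 49 genes of G2/M and mitosis, 46 rose and 1 fell, the same counts as when adjusted over the list alone, with a median of 0.66 (adjusted p = 1.15e-23). The kinetochore gene Cenpf rose by 0.85 ± 0.04, the checkpoint kinase gene Bub1 by 0.77 ± 0.04 and the cell cycle factor Mybl2 by 0.92 ± 0.05. Fibroblast markers followed, with 14 of 16 higher and 1 lower by either adjustment and a median of 1.19 (adjusted p = 7.11e-21); 5 of these 16 genes also belong to the matrix list. The proteoglycan genes Lum (2.25 ± 0.07) and Dcn (1.19 ± 0.04) and the collagen receptor gene Ddr2 (1.49 ± 0.05) rose. These 3 lists kept their call with an estimated correlation, at adjusted p = 0.00780, 0.0385 and 0.00702 in the order given.

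The other 6 called lists did not keep their call with an estimated correlation. Of 44 genes of G1/S and DNA replication, 29 rose and 3 fell (30 and 4 adjusted over the list alone), with a median of 0.19 (adjusted p = 5.30e-05, and adjusted p = 0.278 with an estimated correlation); the thymidine kinase gene Tk1 rose by 0.93 ± 0.05, the histone chaperone gene Chaf1a by 0.66 ± 0.04 and the DNA polymerase alpha gene Pola1 by 0.64 ± 0.04. Of 34 antioxidant and glutathione genes, 22 fell and 3 rose (23 and 3 adjusted over the list alone), with a median of -0.20 (adjusted p = 0.00379, and adjusted p = 0.764 with an estimated correlation). Osgin1, an oxidative stress growth inhibitor, fell by 1.16 ± 0.05 and Gclm, a subunit of the rate-limiting enzyme of glutathione synthesis, by 0.69 ± 0.04, while the epoxide hydrolase gene Ephx1 rose by 0.58 ± 0.04. Of 20 cytosolic heat shock genes, 11 fell and 1 rose by either adjustment, with a median of -0.15 (adjusted p = 0.0299, and adjusted p = 0.966 with an estimated correlation); Hsph1 fell by 0.57 ± 0.03, Dnajb1 by 0.31 ± 0.03 and Bag3 by 0.28 ± 0.04. The heat shock call was lost without Nfe2l1 replicate 1 (adjusted p = 0.0629), with genes of at least 5 mean CPM (0.0672) and with only the 6 libraries compared (0.05004). Over its 17 alternatives this adjusted p ran from 0.00527 to 0.966.

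Markers of other cell types moved with the matrix genes. Of 13 smooth muscle and pericyte markers 9 rose and 1 fell (median 0.34, adjusted p = 0.00454, and adjusted p = 0.102 with an estimated correlation), with Pdgfrb higher by 1.45 ± 0.07, Myh11 higher by 0.82 ± 0.05 and Cspg4 lower at -0.38 ± 0.03. Among 15 endothelial markers 9 rose and 1 fell (median 1.07, adjusted p = 0.00454, and adjusted p = 0.556 with an estimated correlation); the angiopoietin receptor gene Tek rose by 1.77 ± 0.08 and Eng by 1.12 ± 0.04, while Kdr, the main VEGF receptor gene, fell by 1.08 ± 0.04. Of 11 epicardial and mesothelial markers 9 rose and 2 fell (median 1.25, adjusted p = 0.0251, and adjusted p = 0.641 with an estimated correlation), with Upk1b higher by 2.51 ± 0.10 and the keratin gene Krt18 lower at -0.84 ± 0.07. For these 3 lists the counts were the same adjusted over the list alone. The epicardial call was lost without GFP replicate 2 (adjusted p = 0.0568) and with genes of at least 5 mean CPM (0.116). The epicardial adjusted p ran from 3.93e-04 to 0.641 over the alternatives.

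The remaining 24 lists were not called, with medians from -0.30 to 0.57; the signs of median and mean differed in 6 of them, and those of median and test in 4. The sarcomere list had 10 of 28 members higher and 1 lower, with Myom1 at 0.49 ± 0.03 and Cmya5 at -0.42 ± 0.03, and was called without GFP replicate 3 (adjusted p = 0.0345; 0.0345 to 0.986 over the alternatives). In the list of CNC factors and small Maf proteins 1 of 9 genes rose and 7 fell, including Mafg (-0.47 ± 0.04). Keap1, which is in this list but is neither a CNC factor nor a small Maf protein, was among those that fell (-0.30 ± 0.03). Of the 3 NF-Y subunits 1 rose, Nfya itself, and Nfyc stood at -0.01 ± 0.04. Proteasome subunits had 14 of 40 members lower, including Psme4 (-0.29 ± 0.04), and ubiquitin and ER-associated degradation had 4 of 29 higher and 11 lower. Iron handling had 2 of 12 higher and 6 lower, ER chaperones and unfolded protein response 9 of 29 higher and 3 lower, and the ATF4 and amino acid response 8 of 28 in each direction. Cholesterol synthesis had 7 of 24 in each direction, fatty acid and lipid synthesis 4 of 20 higher and 7 lower, fatty acid oxidation 6 of 28 in each direction, and glycolysis 1 of 24 higher and 9 lower, with the lactate exporter gene Slc16a3 at -0.52 ± 0.04. Fetal and stress cardiac genes had 6 of 21 higher and 4 lower. Calcium handling and excitation had 10 of 30 higher and 9 lower, with the L-type calcium channel gene Cacna1c at 0.62 ± 0.03. Oxidative phosphorylation had 3 of 46 higher and 2 lower, and the 35 cytosolic ribosomal protein genes had a median of -0.01. The p53 targets had 6 of 24 higher and 7 lower, apoptosis regulators 6 of 22 higher and 8 lower, and autophagy and lysosome 5 of 34 higher and 9 lower. In the interferon response 10 of 34 rose and 12 fell, with Gbp2 at 1.29 ± 0.07. Among NF-kB and inflammatory mediators 7 of 22 rose and 4 fell, with the adhesion molecule gene Icam1 at 1.20 ± 0.04 and the inhibitor gene Nfkbiz at -1.10 ± 0.05. Macrophage and leukocyte markers had 9 of 13 higher and 2 lower, Schwann and neural markers 2 of 7 higher and 1 lower, and 1 of 3 erythroid markers was higher. Over the 33 lists, counts adjusted over the list alone matched those over all genes in 25.

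**Figure D3:**
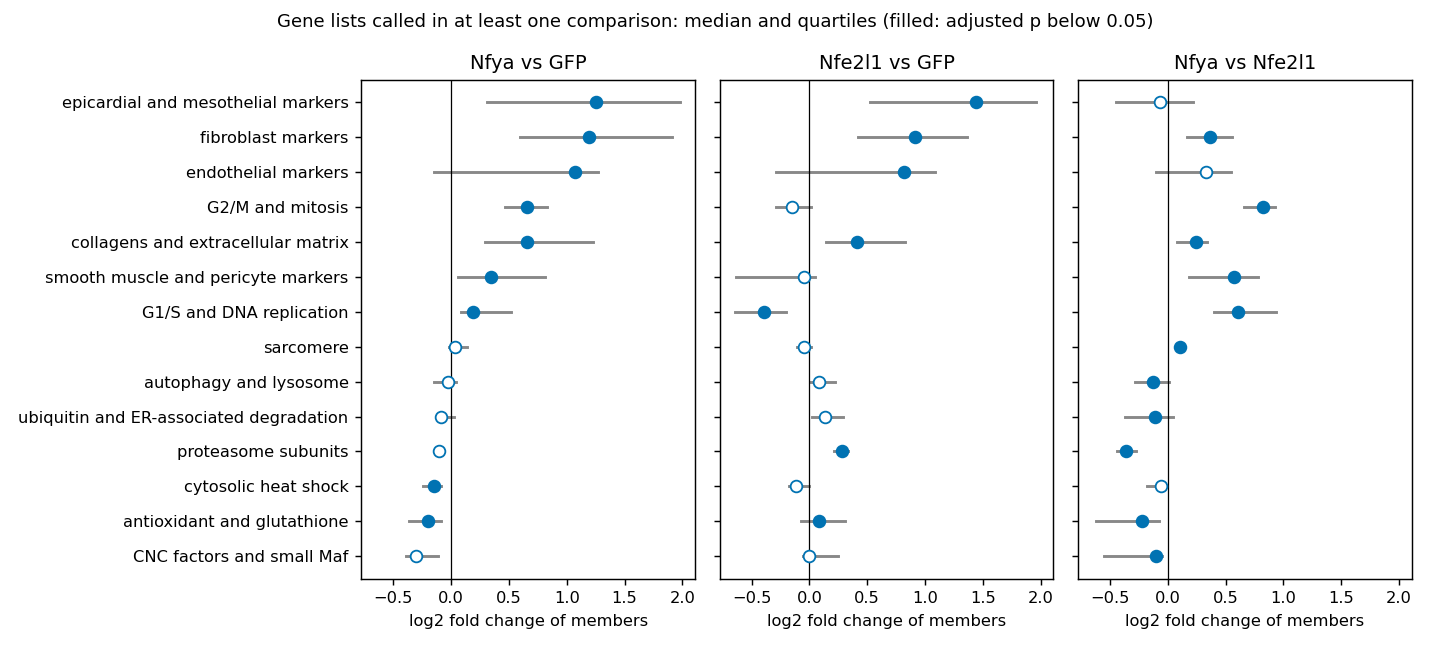
Each panel is 1 comparison, with the log2 fold change of list members on the x axis and the lists called in at least 1 comparison on the y axis. Circles are medians, grey lines the quartiles, and filled circles lists past adjusted p 0.05; the median of G1/S genes is 0.19 for Nfya, -0.39 for Nfe2l1 and 0.61 between them.

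In Nfe2l1-labelled libraries against GFP, which asks what NFE2L1 overexpression changes, 36 of 40 proteasome, 28 of 34 matrix and 17 of 34 antioxidant genes were higher, and 35 of 44 DNA replication genes were lower. The calls of these 4 lists were lost with an estimated correlation (adjusted p = 0.940, 0.0885, 0.940 and 0.142). Slc7a11, the cystine importer that feeds glutathione synthesis, rose from 60.0 ± 8.09 to 224.9 ± 4.86 CPM (SD, n = 3 each). Psmd11, a subunit of the proteasome lid, rose from 178.1 ± 4.99 to 224.7 ± 6.89 CPM. Loxl1, a collagen and elastin cross-linking enzyme, rose from 26.7 ± 2.34 to 105.0 ± 4.75 CPM, and Ccne2, a cyclin of S phase entry, fell from 141.7 ± 3.31 to 80.1 ± 2.08 CPM. Over all genes, edgeR called 4095 higher and 4202 lower, of which 1010 and 717 changed at least 2-fold; the median absolute log2 fold change of called genes was 0.41. The libraries of the 2 groups did not overlap in 9063 genes (64.0%), where chance gives 10%.

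The largest rises in the Nfe2l1-labelled libraries started from levels at or near 0 in GFP. Clec4f, a C-type lectin gene, had 1022 counts in the Nfe2l1-labelled group and 0 in GFP, which makes it at least 320.4-fold higher; Cd52 was at least 58.6-fold and the metallothionein gene Mt3 at least 32.9-fold higher by the same floor of 3 counts over the group. Clca4 had 746 against 2 counts, a ratio of 350.8 with a 95% exact counting interval of 96.8 to 2902. Fetub had 126 against 1 (ratio 118.5, interval 20.9 to 4717), Serpinb3a 193 against 2 (ratio 90.8, interval 24.8 to 754.8) and Add2 135 against 3 (ratio 42.3, interval 14.2 to 207.8). The purinergic receptor gene P2rx6 rose 57.1-fold (log2 fold change 5.84 ± 0.28), the arginine deiminase gene Padi3 41.2-fold from 0.834 ± 0.305 to 35.5 ± 2.80 CPM (5.37 ± 0.19), and the tubulin gene Tubb4a 35.3-fold from 1.25 ± 0.513 to 45.3 ± 1.69 CPM (5.14 ± 0.14, adjusted p = 1.79e-13). Among the falls, Htr3a dropped to 2.66 ± 0.575 CPM (-4.77 ± 0.10, adjusted p = 7.12e-15), and Tsen34l1 and Clec18a each had 110 counts in GFP and 1 in the Nfe2l1-labelled group (ratio 117.0, interval 20.6 to 4661). Cd2 (-4.07 ± 0.33), Cpne6 (-4.03 ± 0.35), Apoa2 (-4.02 ± 0.41), the postsynaptic scaffold gene Dlgap3 (-3.68 ± 0.22), the potassium channel gene Kcng1 (-3.53 ± 0.35), the synaptotagmin gene Syt7 (-3.50 ± 0.20) and Zfp804a (-3.40 ± 0.46) also fell. Serpinb3a, Tubb4a and Tsen34l1 have close paralogs or gene copies, so their counts are uncertain.

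Of the 33 lists, 7 were called, 6 higher and 1 lower, and among them the fibroblast list alone kept its call with an estimated correlation. Fibroblast markers had 13 of 16 members higher by either adjustment, with a median of 0.91 (adjusted p = 1.34e-07, and adjusted p = 0.0376 with an estimated correlation), including Ddr2 (1.39 ± 0.05), Lum (1.34 ± 0.08) and Dcn (0.90 ± 0.04). Collagens and extracellular matrix genes had 28 of 34 higher and 1 lower by either adjustment, with a median of 0.41 (adjusted p = 5.07e-20, and adjusted p = 0.0885 with an estimated correlation); Loxl1 rose by 1.97 ± 0.06, Fbln2 by 1.66 ± 0.04 and Col6a1 by 1.01 ± 0.04. In G1/S and DNA replication 35 of 44 fell and 2 rose (36 and 2 adjusted over the list alone), with a median of -0.39 (adjusted p = 2.78e-09, and adjusted p = 0.142 with an estimated correlation). Ccne2 fell by 0.82 ± 0.04, the replicative helicase genes Mcm6 and Mcm3 by 0.74 ± 0.04 and 0.63 ± 0.04, and the kinase gene Cdk2 by 0.63 ± 0.04. Proteasome subunits had 36 of 40 members higher by either adjustment, with a median of 0.28 (adjusted p = 5.70e-05, and adjusted p = 0.940 with an estimated correlation); Psmb3 rose by 0.45 ± 0.04, Psmc5 by 0.42 ± 0.04, Psmd8 by 0.34 ± 0.03 and Psmd11 by 0.34 ± 0.03. Antioxidant and glutathione genes had 17 of 34 higher and 5 lower by either adjustment, with a median of 0.09 and a mean of 0.42 (adjusted p = 0.0240, and adjusted p = 0.940 with an estimated correlation). Within that list the glutathione peroxidase gene Gpx2 rose by 3.93 ± 0.22, the aldehyde oxidase gene Aox1 by 3.13 ± 0.08 and Slc7a11 by 1.90 ± 0.06, while Gclc, the catalytic subunit of the enzyme that starts glutathione synthesis, fell by 0.43 ± 0.03. This call was lost without Nfe2l1 replicate 2 (adjusted p = 0.0502) and with genes of at least 5 mean CPM (0.0606). Its adjusted p ran from 9.72e-04 to 0.940 over the alternatives.

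Markers of other cell types were again higher beside the matrix genes, though not all. Of 11 epicardial and mesothelial markers 9 rose and 2 fell (median 1.44, adjusted p = 0.00131, and adjusted p = 0.404 with an estimated correlation), with Msln at 4.16 ± 0.25, Upk1b at 2.81 ± 0.09, Krt8 at 1.86 ± 0.05 and the retinoic acid synthesis gene Aldh1a2 at -0.96 ± 0.08. Among 15 endothelial markers 9 rose and 3 fell (median 0.82, adjusted p = 0.0309, and adjusted p = 0.755 with an estimated correlation), with Tek at 1.87 ± 0.08, Eng at 1.36 ± 0.04 and Kdr at -0.86 ± 0.04. For both lists the counts were the same adjusted over the list alone. Smooth muscle and pericyte markers were not called: 3 of 13 rose and 5 fell, with Cspg4 at -0.88 ± 0.03 and Cnn1 at -0.74 ± 0.04. The endothelial call was lost without GFP replicate 3 (adjusted p = 0.0775) and with genes of at least 5 mean CPM (0.0515). The endothelial adjusted p ran from 4.83e-04 to 0.755 over the alternatives.

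In all, 26 lists were not called in this comparison, with medians from -0.29 to 0.52; the signs of median and mean differed in 6, and those of median and test in 5. G2/M and mitosis had 7 of 49 members higher and 24 lower, with the phosphatase genes Cdc25c at 1.06 ± 0.08 and Cdc25b at 0.91 ± 0.05. Ubiquitin and ER-associated degradation had 15 of 29 higher and 4 lower, including Faf2 (0.47 ± 0.03) and Ubqln2 (0.43 ± 0.03), and was called without GFP replicate 3 (adjusted p = 0.0295; 4.83e-04 to 0.892 over the alternatives). Autophagy and lysosome had 16 of 34 higher and 2 lower. In the list of CNC factors and small Maf proteins 4 of 9 genes rose and 1 fell, with Maff at 0.66 ± 0.05. Of the NF-Y subunits 1 of 3, Nfya, rose. Iron handling had 3 of 12 higher and 5 lower, with the metal importer gene Slc39a8 at 1.92 ± 0.09. ER chaperones and unfolded protein response had 11 of 29 higher and 5 lower, the ATF4 and amino acid response 6 of 28 higher and 13 lower, and cytosolic heat shock 3 of 20 higher and 8 lower. Cholesterol synthesis had 8 of 24 in each direction, fatty acid and lipid synthesis 4 of 20 higher and 8 lower, and fatty acid oxidation 4 of 28 higher and 11 lower, with Acadvl at 0.54 ± 0.03. Glycolysis had 1 of 24 higher and 11 lower, with Slc16a3 at -0.79 ± 0.04 and the phosphofructokinase gene Pfkl at -0.54 ± 0.03. The sarcomere list had 3 of 28 higher and 7 lower, fetal and stress cardiac genes 2 of 21 higher and 5 lower with Tnnt1 at -1.71 ± 0.10, and calcium handling and excitation 7 of 30 higher and 13 lower with the potassium channel gene Kcnd3 at -0.91 ± 0.05. Oxidative phosphorylation had 3 of 46 higher and 4 lower, and cytosolic ribosomal proteins 7 of 35 lower. The p53 targets had 7 of 24 higher and 5 lower, with Plk3 at 1.16 ± 0.08, and apoptosis regulators 8 of 22 higher and 6 lower, with Diablo at 0.71 ± 0.05. In the interferon response 6 of 34 rose and 18 fell, and the list was called without GFP replicate 1 (adjusted p = 0.0262, the lowest over the alternatives, with 0.940 the highest). NF-kB and inflammatory mediators had 9 of 22 in each direction, with the chemokine gene Ccl2 at 1.70 ± 0.07. Macrophage and leukocyte markers had 4 of 13 higher and 1 lower, and 1 of 3 erythroid markers was higher. Schwann and neural markers had 4 of 7 higher and 1 lower, with S100b at 2.42 ± 0.16, and were called without Nfya replicate 2 (adjusted p = 0.0483), without Nfya replicate 3 (0.0474) and with only the 6 libraries compared (0.0289), with a range of 5.51e-06 to 0.379 over the alternatives. Over the 33 lists, counts adjusted over the list alone matched those over all genes in 26.

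The direct comparison of Nfya- with Nfe2l1-labelled libraries tests whether the effects of the viruses differ. Cell cycle genes were higher in the Nfya-labelled libraries, and 37 of 40 proteasome and 22 of 34 antioxidant genes higher in the Nfe2l1-labelled ones, though with an estimated correlation the calls of these last 2 lists were lost (adjusted p = 0.423 and 0.161). Uhrf1, which maintains DNA methylation through replication, stood at 138.1 ± 1.58 CPM in the Nfya-labelled and 54.97 ± 3.92 CPM in the Nfe2l1-labelled libraries, with 92.2 ± 2.49 CPM in GFP (SD, n = 3 each). Slc7a11 stood at 42.5 ± 2.58 CPM in the Nfya-labelled and 224.9 ± 4.86 CPM in the Nfe2l1-labelled libraries. Over all genes, edgeR called 3561 higher and 3597 lower in the Nfya-labelled libraries, of which 457 and 501 differed at least 2-fold; the median absolute log2 fold change of called genes was 0.35. The libraries of the 2 groups did not overlap in 8495 genes (60.0%), where chance gives 10%.

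The 5 genes furthest above the Nfe2l1-labelled level were Shisa3 (6.27-fold, log2 fold change 2.65 ± 0.26), Tmem229a (5.86-fold, 2.55 ± 0.33), the p53 family gene Tp73 (4.78-fold, 2.26 ± 0.30), Lrr1 (4.66-fold, 2.22 ± 0.18) and the proto-oncogene Myb (4.48-fold, 2.16 ± 0.21). The 5 furthest below were Clec4f (2 against 1022 counts, ratio 502.5 with a 95% exact counting interval of 138.8 to 4155), Crisp3 (0 against 135 counts, at least 44.3-fold lower), Mt3 (1 against 105 counts, ratio 103.3, interval 18.1 to 4117), Lexm and Serpinb3a (3 against 193 counts, ratio 63.3, interval 21.3 to 309.5). Lexm stood at 0.760 ± 0.459 CPM in the Nfya-labelled and 45.1 ± 0.501 CPM in the Nfe2l1-labelled libraries (-5.86 ± 0.16, adjusted p = 2.60e-13).

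Of the 33 lists, 11 were called in the direct comparison, 6 higher and 5 lower in the Nfya-labelled libraries. The lists kept with an estimated correlation were G2/M and mitosis, G1/S and DNA replication, and smooth muscle and pericyte markers, at adjusted p = 0.0263, 0.0164 and 0.0164. Mitotic genes were higher in 44 of 49 cases and lower in 2 by either adjustment, with a median of 0.82 (adjusted p = 2.03e-35); the mitotic transcription factor gene Foxm1 differed by 1.08 ± 0.04 and the proliferation marker Mki67 by 0.81 ± 0.03. Replication genes were higher in 41 of 44 cases and lower in 1 (42 and 1 adjusted over the list alone), with a median of 0.61 (adjusted p = 1.33e-34); Mcm10 differed by 1.37 ± 0.05, Uhrf1 by 1.32 ± 0.04 and Pold1 by 1.23 ± 0.05. Smooth muscle and pericyte markers were higher in 11 of 13 cases by either adjustment, with a median of 0.57 (adjusted p = 9.61e-08); Cnn1 differed by 0.87 ± 0.04 and Myh11 by 0.78 ± 0.05. Matrix genes were higher in 23 of 34 cases and lower in 2 (24 and 2 adjusted over the list alone), with a median of 0.25 (adjusted p = 1.65e-11, and adjusted p = 0.161 with an estimated correlation), including Tnc (0.98 ± 0.03) and Vcan (0.92 ± 0.03). Fibroblast markers were higher in 11 of 16 cases (12 adjusted over the list alone), with a median of 0.36 (adjusted p = 0.00181, and adjusted p = 0.0732 with an estimated correlation), including Lum (0.91 ± 0.05). Sarcomere genes were higher in 14 of 28 cases by either adjustment, with a median of 0.10 (adjusted p = 0.0374, and adjusted p = 0.955 with an estimated correlation), including Myom1 (0.25 ± 0.03), the alpha myosin heavy chain gene Myh6 (0.23 ± 0.04) and Xirp1 (0.16 ± 0.03). The sarcomere call was lost without Nfe2l1 replicate 3 (adjusted p = 0.0924), Nfya replicate 1 (0.0564) or Nfya replicate 2 (0.0527), with a replicate block (0.0620) and with fry (0.0669). Here the adjusted p ran from 0.00451 to 0.955 over the alternatives. Sarcomere genes are densely covered (median 0.63 counts per base), and in each group their level was lowest in the deepest library. Their median log2 deviation from the mean of all libraries was 0.093 in GFP replicate 3 (shallowest) and -0.053 in replicate 2 (deepest). In the Nfe2l1-labelled group it was 0.018 in replicate 2 (shallowest) and -0.144 in replicate 3 (deepest). An effect of depth may therefore contribute, which was not tested.

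Protein degradation and redox lists were lower in the Nfya-labelled libraries, and none of the 5 kept its call with an estimated correlation. Proteasome subunits were lower in 37 of 40 cases by either adjustment, with a median of -0.36 (adjusted p = 1.43e-13, and adjusted p = 0.423 with an estimated correlation), including Psmb3 (-0.59 ± 0.04), Psmd11 (-0.56 ± 0.03) and Psmd3 (-0.45 ± 0.03). Antioxidant and glutathione genes were lower in 22 of 34 cases and higher in 1 by either adjustment, with a median of -0.22 (adjusted p = 1.21e-11, and adjusted p = 0.161 with an estimated correlation), including Slc7a11 (-2.40 ± 0.06), Aox1 (-2.38 ± 0.07) and Gclm (-0.85 ± 0.04). Ubiquitin and ER-associated degradation genes were lower in 13 of 29 cases and higher in 3 by either adjustment, with a median of -0.11 (adjusted p = 0.00882, and adjusted p = 0.366 with an estimated correlation); Ngly1, the deglycosylase known to act on NFE2L1, differed by -0.52 ± 0.04. Genes in the list of CNC factors and small Maf proteins were lower in 5 of 9 cases by either adjustment, with a median of -0.10 (adjusted p = 0.0115, and adjusted p = 0.285 with an estimated correlation). These included Maff (-1.05 ± 0.06), Mafg (-0.63 ± 0.04) and Keap1 (-0.55 ± 0.03), which is neither a CNC factor nor a small Maf protein. Autophagy and lysosome genes were lower in 17 of 34 cases and higher in 3 (18 and 4 adjusted over the list alone), with a median of -0.13 (adjusted p = 0.0144, and adjusted p = 0.455 with an estimated correlation), including the autophagy kinase gene Ulk1 (-0.56 ± 0.04) and the proton pump gene Atp6v1h (-0.51 ± 0.04).

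The other 22 lists were not called in the direct comparison, with medians from -0.25 to 0.33; the signs of median and mean differed in 1, and those of median and test in 3. Calcium handling and excitation had 13 of 30 members higher and 1 lower (adjusted p = 0.0565), including Asph (0.39 ± 0.03), and was called without any 1 GFP library (adjusted p = 0.0423, 0.0410 and 0.0220 without replicates 1, 2 and 3) and without Nfe2l1 replicate 2 (0.0231). It was also called with RLE size factors (0.0485), with genes of at least 5 mean CPM (0.0499) and with only the 6 libraries compared (0.0475), with a range of 9.55e-04 to 0.443 over the alternatives. The interferon response had 15 of 34 higher and 3 lower (adjusted p = 0.0622), with Gbp5 at 1.08 ± 0.10, and was called without any 1 GFP library (0.0423, 0.0417 and 0.0401), without Nfe2l1 replicate 3 (0.0477), without Nfya replicate 2 (0.0268) and with only the 6 libraries compared (0.0336), with a highest value of 0.955 over the alternatives. Schwann and neural markers had 1 of 7 higher and 4 lower (adjusted p = 0.0608), with Tubb3 at -1.58 ± 0.06, and were called without GFP replicate 1 (0.0430) or 2 (0.0454) and with genes of at least 5 mean CPM (0.0196), with a range of 3.59e-05 to 0.278 over the alternatives. Endothelial markers had 7 of 15 higher and 3 lower, with Egfl7 at -1.34 ± 0.11, and epicardial and mesothelial markers 1 of 11 higher and 3 lower, with Krt8 at -1.59 ± 0.05. Macrophage and leukocyte markers had 2 of 13 in each direction, and erythroid markers 1 of 3 in each direction, with Epb42 at -3.09 ± 0.39. Of the 3 NF-Y subunits, Nfyb stood at 0.09 ± 0.04 and did not pass the test. Iron handling had 2 of 12 higher and 4 lower, with Hmox1 at -0.93 ± 0.05. The ATF4 and amino acid response had 11 of 28 higher and 6 lower, with the arginine importer gene Slc7a1 at 0.67 ± 0.03. ER chaperones and unfolded protein response had 9 of 29 higher and 7 lower, and cytosolic heat shock 7 of 20 lower. Cholesterol synthesis had 7 of 24 higher and 4 lower, fatty acid and lipid synthesis 7 of 20 higher and 6 lower, fatty acid oxidation 11 of 28 higher and 4 lower, and glycolysis 3 of 24 in each direction. Fetal and stress cardiac genes had 8 of 21 higher and 1 lower, oxidative phosphorylation 3 of 46 higher and cytosolic ribosomal proteins 2 of 35 higher. The p53 targets had 5 of 24 in each direction, with Plk3 at -1.25 ± 0.08, apoptosis regulators 4 of 22 higher and 6 lower, and NF-kB and inflammatory mediators 9 of 22 higher and 4 lower. Over the 33 lists, counts adjusted over the list alone matched those over all genes in 22.

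The changes against GFP overlapped between the viruses. Tek, Fbln2, Postn and Upk1b rose, and Htr3a, Cd2, Cpne6, Kdr and Nfkbiz fell, in both comparisons. In all, 4576 genes were called in the same direction in both, 2099 higher and 2477 lower, where independent lists of these sizes would share 993 and 1174. Another 777 genes were called in opposite directions, where independent lists would give 2163. All 777 also passed the direct test between the viruses. That adds little, because for opposite changes the direct difference is larger than either change against GFP. Among them, Lexm changed by -3.71 ± 0.24 in the Nfya-labelled and by 2.15 ± 0.09 in the Nfe2l1-labelled libraries, and Gpx2 by -1.67 ± 0.50 and 3.93 ± 0.22. Both comparisons use the same 3 GFP libraries, which alone makes their fold changes correlate. Across genes, which are not independent replicates, the Pearson correlation of the fold changes was 0.66, against a mean of 0.51 in 20 simulations of unchanged groups against the same controls; their covariance was 0.36 against a simulated 0.0116, a difference of 0.35. The fold changes had the same sign in 70.4% of genes, against 67.1% in the simulations. The simulated groups held no effects. Their correlation and share of equal signs therefore do not say how much of the observed values comes from the shared controls. The 3 control libraries were not split, since 1 part would hold a single library, so part of the excess may come from the shared libraries, and 2084 of the 4576 genes also differed between the viruses in the direct test.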

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

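The splits of the libraries and the test of coverage over all 3 groups were planned before their results were seen. So were the gene and list tests repeated here from the comparisons above. The other tests in this part were chosen afterwards. Splitting the 6 libraries of a comparison into 3 and 3 gives 10 splits, too few for a share under 0.05. Every split but the one by label mixes the groups, so a difference between them adds to the spread and lowers the calls. The split by label alone (1 of 10 in each comparison) gave 7386, 8297 and 7158 called genes for Nfya against GFP, Nfe2l1 against GFP and Nfya against Nfe2l1, and the highest other split gave 0 in each with edgeR, where up to 281, 828 and 246 genes had an unadjusted p below 0.05.

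The transcript of Nfya rose by only 0.15 against GFP in the libraries labelled for it, where it was not called above its level in the Nfe2l1-labelled ones, and Nfe2l1 was not called against GFP in its own. A ceiling on counts would leave room for a rise. Among genes covered like Nfya, the 99th percentile of changes in the Nfya-labelled libraries against GFP was 0.93 and the highest 1.63 (Tnc). Nfya itself differed by -0.054 between the Nfya- and Nfe2l1-labelled libraries. The change of Nfe2l1 against GFP was -0.0075, where the 99th percentile of genes covered like it was 0.34. A construct from another species, or one whose reads were not assigned to the rat gene, cannot be told apart from a lack of expression by the counts at that gene, which need not carry it, and no reads or construct sequences are at hand. If neither virus expressed its factor, the virus groups would be alike unless cultures or virus preparations differed. Between them 7158 genes were called, but different viruses are necessarily different preparations, and the labels name no separate cultures. The labels give the dose as a volume, 8 uL of virus with 1 mL of medium for every library. A difference between preparations therefore cannot be told apart from an effect of the factors. Overexpression of each factor, the labels' own explanation, therefore stays open and untested at the level of its transcript. Because the counts need not carry a construct, the Nfe2l1 transcript, at -0.10 in the Nfya-labelled against the Nfe2l1-labelled libraries, cannot decide whether these labels were exchanged; proteasome genes, known to be induced by NFE2L1, were lower there in 37 of 40 cases (median -0.36, adjusted p = 1.43e-13, and 0.423 with an estimated correlation), the direction the labels call for, but what either virus does to them in these cells is not known apart from these labels.

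Fibroblast, endothelial and epicardial markers were higher in both virus groups, with 50 of 68 markers of 5 other cell types called higher and 7 lower for Nfya and 38 higher and 11 lower for Nfe2l1; with an estimated correlation the endothelial (adjusted p = 0.556 and 0.755) and epicardial (0.641 and 0.404) calls were lost in both. A larger share of all those types in equal proportion would raise their markers alike. A larger share of some types alone would not. For Nfe2l1 the 5 lists moved apart (medians -0.04 to 1.44, permutation p = 0.00213 for the Kruskal-Wallis statistic). That test takes each marker as specific to its cell type and the genes as independent of each other, and neither was tested. A marker that myocytes also express would lag under an equal rise. The test therefore cannot decide between an equal rise of all 5 types and a larger share of some. For Nfya a common rise cannot be told apart from separate ones, because members of each list spread widely. There the medians ran from 0.34 to 1.25 and the permutation p of the same statistic was 0.0948. GFP libraries that alone stood apart would leave the fibroblast list level between the viruses, and 11 of its 16 members were higher and none lower for Nfya, with a median of 0.36 (adjusted p = 0.00181, 1.08e-05 with fry and 0.0732 with an estimated correlation), which argues against that as the whole cause. A larger share of some or all of these cell types and a change of state in fibroblasts or myocytes stay open as hypotheses, and neither was settled.

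Only 14 genes exceeded 1 count per base of gene length. Independent reads would scatter with a chi-square per gene of at least 1 between replicates: in genes above 0.5 counts per base the median over 3 replicate pairs was 0.584 in the Nfya-labelled and 0.714 in the Nfe2l1-labelled group, which argues against them there, while in GFP it was 1.14 and they cannot be told apart from limited counts, because variation between libraries adds to it. Counting reads at the same position once is a candidate explanation: where replicates differed in depth by over 1.1 times (GFP and Nfe2l1), the shallower library held the larger share in dense genes by at least 0.22. In the Nfya-labelled group the difference was -9.04e-04, and that group decides nothing because its depths differ by a factor of only 1.03. Fold changes of abundant transcripts may therefore be too small, or shifted where the libraries compared differ in depth. No biological explanation was tested for this pattern.

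Lists were flagged when called in opposite directions against GFP for the viruses and also called in the direct test. The direct call was thus part of the choice and adds no separate evidence. In G1/S and DNA replication 29 of 44 genes rose and 3 fell for Nfya, and 2 rose and 35 fell for Nfe2l1, calls that were lost with an estimated correlation (adjusted p = 0.278 and 0.142). The direct call, which the choice required, had a median of 0.61 between the viruses (adjusted p = 1.33e-34). It was kept with an estimated correlation (adjusted p = 0.0164). Of 34 antioxidant and glutathione genes 3 rose and 22 fell for Nfya, and 17 rose and 5 fell for Nfe2l1, with a median of -0.22 between them (adjusted p = 1.21e-11). With an estimated correlation these 3 calls were lost (adjusted p = 0.764, 0.940 and 0.161).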

How the results depend on the processing

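Only the inversion of the count ceiling was chosen after the data were seen. Of 289 called results for named genes none reversed under 24 settings, and 112 kept their call in all, counting only settings that tested the gene. Requiring an absolute log2 fold change of 1, a cut on effect size, removed the call of 176. Apart from the targeted genes, these were named for large changes or small p in the same libraries, so an absence of reversals adds little. Filters on low counts or RPKM, and leaving out the targeted genes, removed some genes from a setting. Of 27 called lists none reversed under 17 settings, and 7 kept their call in all. Requiring an absolute log2 fold change of 1 left 916 higher and 481 lower genes for Nfya against GFP, 1010 and 717 for Nfe2l1 against GFP, 457 and 501 for Nfya against Nfe2l1, and 900 genes changed in the same direction by both viruses; that criterion itself removes smaller changes. The DESeq2 Wald test called 2610 higher and 2486 lower genes for Nfya against GFP. It called 3217 and 3048 for Nfe2l1 against GFP, and 2437 and 2392 for Nfya against Nfe2l1. Its overlap in the same direction was 3067 genes. All these counts were below those of edgeR, and the cause was not tested. With an estimated correlation 3, 1 and 3 lists were called in the same order, and with fry 16, 20 and 17; fry tests another hypothesis. Leaving out 1 library gave 3155 to 3915 higher and 3059 to 4034 lower genes for Nfya against GFP, 3878 to 4112 and 3666 to 4215 for Nfe2l1 against GFP, 3150 to 3861 and 2984 to 3703 for Nfya against Nfe2l1, 4108 to 4455 genes in the same direction for both, and 8 to 10, 6 to 8 and 10 to 14 called lists. The replicate numbers showed no pairing of the libraries: over 11941 genes, correlations of 9 same-number pairs ran from -0.139 to 0.0913. Of all libraries, 0 correlated best with their own number in both other groups. Replicates scattered little beyond counting error (chi-square per gene of 1.01 to 1.69 over all genes), so these correlations cannot exclude a pairing. With a replicate block, 3371 and 3849, 4040 and 4097, and 3428 and 3501 genes were higher and lower, 4448 went in the same direction, and 9, 7 and 10 lists were called. With the assumed ceiling inverted, which may correct too little, the counts were 3541 and 4177, 4276 and 4354, and 3730 and 3796. More genes were lower than higher in each comparison as reported, and this balance turned over in 9, 9 and 12 of 24 alternatives. Depth limits genes at few counts, where only bounds or wide intervals could be given.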

Other observations

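The genes in this part were chosen after their values were seen, and no set of them was tested as a set. Of 8 genes of enzymes that carry or make the molybdenum cofactor, 6 were higher and 2 lower in the Nfe2l1-labelled libraries than in GFP. Mocos, the sulfurase that activates the cofactor of aldehyde and xanthine oxidases, rose from 4.18 ± 0.762 to 76.9 ± 3.27 CPM (SD, n = 3 each; log2 fold change 4.18 ± 0.09). The aldehyde oxidase genes Aox1 and Aox2 rose by 3.13 ± 0.08 and 3.79 ± 0.31 and have close paralogs, the xanthine dehydrogenase gene Xdh rose by 1.15 ± 0.07, and the cofactor synthesis genes Mocs1 and Mocs2 by 0.89 ± 0.07 and 0.35 ± 0.05. Suox, the sulfite oxidase gene, fell by 0.60 ± 0.07 and Gphn, which completes the cofactor, by 0.15 ± 0.05. Of 6 genes of one-carbon and glycine metabolism 4 rose and 1 fell. Gldc, the glycine decarboxylase, rose from 3.00 ± 0.864 to 48.7 ± 2.29 CPM (4.01 ± 0.12), Mat1a, a methionine adenosyltransferase best known from liver, from 4.43 ± 0.597 to 79.1 ± 3.24 CPM (4.15 ± 0.11), Aldh1l1 by 4.19 ± 0.16 and Amt by 0.56 ± 0.13. The widely expressed Mat2a fell by 0.16 ± 0.05, and Gcsh (-0.04 ± 0.04) did not pass the test. In the Nfya-labelled libraries Mocos and Aldh1l1 also rose against GFP, by 1.23 ± 0.15 and 2.15 ± 0.21. There 4 of the 8 genes rose and 2 fell (Suox at -0.24 ± 0.06 and Gphn at -0.24 ± 0.05), and 2 of the 6 rose and 1 fell (Gcsh at -0.16 ± 0.05).

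Of 15 genes of microtubules and axonal transport, 9 rose in the Nfe2l1-labelled libraries and 6 were not called. The kinesin gene Kif5c rose from 2.39 ± 0.902 to 49.1 ± 1.58 CPM (4.33 ± 0.13), the dynein intermediate chain gene Dync1i1 from 1.61 ± 0.444 to 46.4 ± 2.08 CPM (4.86 ± 0.13) and Dnajc6, the neuronal auxilin, from 2.27 ± 0.964 to 51.9 ± 2.46 CPM (4.54 ± 0.13). The tubulin genes Tubb3 (1.43 ± 0.06), Tubb2b (1.77 ± 0.18) and Tubb2a (1.11 ± 0.11) rose as well, while Tubb5 (0.00 ± 0.04), Tubb6 (-0.08 ± 0.03), Tuba4a (-0.07 ± 0.04), Tuba8 (-0.14 ± 0.41), Kif5b (0.07 ± 0.04) and Kif5a (0.08 ± 0.10) did not pass the test; tubulin paralogs share sequence, so single values are uncertain. In the direct comparison Kif5c, Dync1i1 and Dnajc6 were lower in the Nfya-labelled libraries, by -3.10 ± 0.10, -3.73 ± 0.11 and -3.18 ± 0.11. They nevertheless rose in the Nfya-labelled libraries against GFP too, by 1.23 ± 0.21, 1.13 ± 0.25 and 1.36 ± 0.23, as did Tubb2b by 1.56 ± 0.18. Of the 15 genes 7 rose and 3 fell there, with Kif5a lower at -1.87 ± 0.14, Dync1i2 at -0.11 ± 0.03 and Tubb6 at -0.10 ± 0.03.

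Some genes varied widely within groups. Hspa1b stood at 248.8, 154.7 and 50.4 CPM in GFP replicates 1, 2 and 3, and at 44.3, 11.1 and 85.2 CPM in the Nfe2l1-labelled replicates. Col1a2 ran from 0.919 to 17.3 CPM within GFP, far below its partner chain Col1a1 at 501.5 CPM, and its count is uncertain. The interferon-induced genes Mx2 and Usp18 stood at 65.0 and 27.0 CPM in GFP replicate 2, against 19.2 and 9.81 CPM in replicate 1 and 37.3 and 15.4 CPM in replicate 3.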
